A study of Mus musculus with 2 samples.

How the data were processed

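The deposited peak lists, footprint lists and FDR tracks of 2 DNase-seq libraries on mouse build mm10 were used without changing their values. The signal of a peak is the authors' own value for DNase cutting at that peak, called by the depositing consortium from the alignment of that library alone and not from pooled reads. Its scaling is not given in the sources used here, and the signal was therefore compared within a library, as a percentile, or as a ratio of libraries relative to their median ratio. The FDR values per base and the footprint threshold, constant at 0.01, are the authors' own, as deposited. The FDR track lists bases with an FDR under 0.05 and was derived from each library's alignment. Aligner, peak caller, footprint caller and their versions are not given in the sources used here. Reads were not analysed here.

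Each library had 2 peak lists in the same format. In the strict list every peak held at least 1 base with an FDR of 0.001 or less, and in the permissive list the lowest FDR per peak reached 0.05. In the permissive lists 62.2% and 65.6% of peaks reached 0.001. The strict list served throughout and the permissive list as the alternative, a choice made after the files were seen and before any test was run. Per the labels, the 2 libraries are biological replicates of 1 group, replicate 1 was sequenced on 2 instrument models, and both name the same donor entry.

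The gene lists, motif consensus sequences, windows, tests and most alternatives were fixed before the data were examined. Genes were taken from GENCODE M21 (basic set), with 21911 protein-coding symbols, where 54 genes that shared a symbol were kept once per symbol, and 20870 of 20876 symbols lay at the same place in RefSeq. A promoter was the window of 1 kb on either side of any annotated start of the gene, and its signal was that of the strongest overlapping peak. A gene counted as open if it had a promoter peak in both libraries. Genes were compared by percentile of promoter signal in each library, averaged over libraries. A distal region was a merged region with peaks in both libraries and outside all promoter windows, and it was counted for a gene if it lay within 50 kb of a start of the gene. Peak classes were assigned in the order promoter, exon, intron and intergenic.

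The 24 gene lists contained 425 members by symbol, of which 422 were used. They cover fibre types, contractile and metabolic machinery, regulators, satellite cells and the neuromuscular junction, other cell types of the tissue, and tissues from outside it. Some genes stand in more than 1 list, such as Pax7, Des and Gpd1. Ahsp and Tp63 were not found under those symbols, and H19 is a noncoding gene (promoter signal 3.39 and 1.36).

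Open shares were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Wilson intervals for the shares. Promoter signal and distal regions were compared with 10000 random gene lists of the same size, the distal lists matched on gene length in 10 bins. Motif matches on either strand were counted in footprint bases and in the remaining bases of the same peaks, and compared by Fisher's exact test, with 10 column-shuffled versions of each consensus as controls. A motif was called if it passed in both libraries in the same direction. Benjamini-Hochberg adjustment was applied within each family of tests, over 24 lists or 25 motifs, at a level of 0.05. Random placement of peaks was within chromosomes, outside assembly gaps, 100 times.

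Genes named in the text follow a fixed rule. For each list these are up to 3 members with the highest mean promoter percentile among those open in both libraries, and up to 2 members without a promoter peak in either. Added to these are all myogenic regulators, the myosin genes Myh1, Myh2, Myh3, Myh4, Myh7 and Myh8, the 10 members of muscle lists with most distal regions, and the 5 strongest regions. Some of the genes that the rule selects, and 1 of the 25 motifs, are not reported here.

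Alternatives were promoter windows of 250 and 2500 bases, distal windows of 20 and 100 kb, the permissive list, the peaks at or above the median signal of their library, a reciprocal overlap of 50%, footprints wholly inside a peak, motif background within 50 bases of footprints, random lists matched on CpG ratio or on neighbouring genes, and each library alone. Kilobases covered, motif matches counted at their central base, and single-library values for peak counts, peak classes, footprints and chromosome X were added after the data were examined.

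The list tests were run on simulated lists with known effects (20 rounds). Raised lists were recovered in 82.5% of cases for open shares, 60.0% for promoter signal and all cases for distal regions. Lists without an effect were called in 1.56%, 2.19% and 0.313% of cases. Raised lists had an open share of 95% against 60%, percentiles of 60 to 100, or a mean of 6 regions against 3. The simulated genes had no tied signals, and their distal regions were drawn independently for each gene. Real genes can share regions and closed promoters tie, so these rates need not hold for the real lists. All 8000 implanted motif matches and all 7458 overlaps in test intervals were found.

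Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, pysam 0.24.0 and bedtools 2.31.1.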

Results

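DNase I cuts DNA where it is not wrapped tightly around nucleosomes, so sequencing the cut ends (DNase-seq) marks open chromatin. Within an open site, short stretches that escape cutting are called footprints and are taken to mark bases shielded by a bound protein. Neither binding itself nor any sequence preference of the enzyme was examined here. The assay was applied to gastrocnemius, the large calf muscle of the hind limb, which in the mouse consists mostly of fast-contracting fibres and also holds satellite cells, vessels, nerve, connective tissue and blood cells. The animals were male B6CASTF1/J mice aged 14 days, hybrids of the laboratory strain C57BL/6 with the wild-derived strain CAST. The labels give 1 group with 2 biological replicates and carry the words 3x Males without explaining them, so how many animals went into each library is not known. No condition was contrasted, so values are given per library, in the order replicate 1 and replicate 2, and ± denotes the SD over the 2 libraries (n = 2). Tests run across genes or regions, which are not independent replicates.

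Open regions were concentrated at promoters relative to random placement, although introns held the largest share of all peaks. Among peaks at or above the median signal, promoters held the largest share in both libraries (44.5% and 39.7%), ahead of introns. The region with the highest mean percentile of signal over the 2 libraries lay at the promoter of Hjurp, which loads the centromeric histone. It spans chromosome 1 from 88277521 to 88277760 (build mm10), with peak signals of 47.4 and 23.7. That was the highest signal in replicate 1 but not in replicate 2, where the maximum was 78.7. Next were the promoter of the dynein light chain gene Dynlt1b (chromosome 17, 6430021 to 6430180, signals 45.2 and 22.2) and an exonic site nearest to Cox14, a gene for cytochrome oxidase assembly, at 10253 bases from its start (chromosome 15, 99735661 to 99736080, signals 32.5 and 30.6). The promoters of Bahcc1 (chromosome 11, 120232681 to 120232880, signals 36.3 and 16.9) and Mplkip (chromosome 13, 17694881 to 17695100, signals 37.9 and 13.9) completed the top 5. Among all peaks, 31.9% and 29.5% lay within 1 kb of an annotated start (mean 30.7 ± 1.69%), against 4.53% and 4.50% after random placement, a 7.04- and 6.56-fold excess. Introns held 35.6% and 36.4% of peaks, exons 5.02% and 4.40%. Intergenic sequence held 27.4% and 29.7%, which was 0.548 and 0.592 times the share of random placements. Promoter peaks had a median signal of 2.45 and 1.45, and intergenic peaks 1.03 and 0.720. With a promoter window of 250 bases the promoter share was 18.8%.

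The libraries contained 82498 and 88198 peaks (mean 85348 ± 4031) with a median width of 180 bases, covering 15.3 and 17.3 Mb, or 0.561% and 0.635% of the genome. Footprints numbered 320456 and 384435 (mean 352445.5 ± 45240), with a median length of 10 bases. The files give no read totals. Every signal value in each library was a whole multiple of a small step (within 0.05 of a step), which would correspond to 179 and 218 M tags (M as in Mb) if the signal were scaled per M tags. That scaling is not given in the sources used here. The permissive list of each library, which admits peaks up to an FDR of 0.05, held 138117 and 139545 peaks.

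Of the peaks of each library, 79.2% and 73.9% overlapped a peak of the other by at least 1 base (mean 76.5 ± 3.78%), against 1.36% and 1.27% after random placement. Across genes the Spearman correlation of promoter signal was 0.970, to which genes without a peak in either library contribute as ties, and single open genes ranked apart, such as Myl4 (percentiles 75.9 and 99.5). Over 65340 shared peaks the Spearman correlation of signal was 0.824 and Pearson's r on the log2 scale 0.857, both across regions rather than samples. The median ratio of replicate 1 to replicate 2 was 1.54, and 86.2% of pairs lay within 2-fold of it. Peaks found in only one library had median signals of 0.730 and 0.482 against 1.55 and 1.10 for shared peaks, and 89.9% and 87.7% of all peaks had a counterpart in the permissive list of the other library. Since the labels do not say whether the libraries came from separate animals, this spread may be partly technical.

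Promoters of energy metabolism, of calcium release and of the sarcomere and membrane were open in both libraries more often than those of other protein-coding genes. All 23 genes of oxidative metabolism carried a promoter peak in both libraries, as did 19 of 20 genes of glycogen use and glycolysis, 15 of 16 genes of excitation-contraction coupling (the release of calcium that follows a nerve impulse) and 24 of 28 genes of the sarcomere, Z disc and muscle membrane. Across the 21911 protein-coding genes, 13512 promoters (61.7%) were open in both libraries. Examples with the strongest promoters were Gys1, the muscle glycogen synthase, with signals of 22.8 and 11.4 (percentile among genes 99.6 ± 0.077), the nuclear receptor gene Esrra with 26.7 and 10.1 (percentile 99.5 ± 0.562), and Mtmr4 of the coupling list, a lipid phosphatase gene, with 20.5 and 7.90 (percentile 97.3 ± 2.25). Pkm, a pyruvate kinase, had signals of 11.6 and 5.82, Ppard, a nuclear receptor of fat oxidation, 15.1 and 8.19, and Idh3a of the citric acid cycle 16.8 and 7.33. In the coupling list, Bin1, which shapes the T tubules, had 11.2 and 4.40 and Asph, the source of junctin, 12.1 and 4.88. In the sarcomere list Des, the desmin gene, had 9.49 and 2.16, Sgcb, a sarcoglycan, 5.71 and 3.34, and Actn2, an actinin of the Z disc, 6.53 and 2.01. Ampd1, the AMP deaminase of muscle, Scn4a, its voltage-gated sodium channel, and Smpx, a small X-linked muscle protein gene, had no promoter peak in either library.

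The share of open promoters was higher than among all other protein-coding genes for 6 of 24 lists (Fisher's exact test, two-sided, Benjamini-Hochberg over the 24 lists): oxidative metabolism (23 of 23, q = 8.1e-05), glycogen and glycolysis (19 of 20, q = 0.0056), pericytes and smooth muscle (14 of 14, q = 0.0056), coupling (93.8%, q = 0.0213), sarcomere and membrane (85.7%, q = 0.0242) and ubiquitous genes (26 of 26, q = 3.5e-05). Among the ubiquitous genes, the translation factor Eef2 had signals of 16.9 and 12.5, the ribosomal gene Rplp0 14.8 and 12.6, and Actb 14.4 and 8.01. Among the pericyte and smooth muscle genes, Cspg4, a pericyte proteoglycan, had 4.33 and 2.20, Myh11, the smooth muscle myosin, 2.77 and 2.52, and Tagln 2.24 and 2.53. In peaks at or above the median signal of their library, the share passed for myogenic regulators (q = 0.0256). There the calls for sarcomere (q = 0.851), coupling (q = 0.0838), oxidative metabolism (q = 0.0518) and pericyte genes (q = 0.401) ended, and with a window of 250 bases the sarcomere call ended (75.0% open, q = 0.147).

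Fast fibre genes were open at 17 of 20 promoters, slow fibre genes at 7 of 16 and developmental contractile genes at 8 of 14, and none of these shares passed the test (q = 0.0683, 0.278 and 0.858). In the fast list Tpm1, a tropomyosin, had promoter signals of 14.9 and 8.74, Mybpc2, the fast myosin-binding protein, 9.98 and 5.05, and Actn3, the actinin of fast fibres, 9.59 and 5.13. In the slow list Myl6b, a myosin light chain, had 11.6 and 4.40, Atp2a2, the calcium pump of slow fibres and heart, 6.71 and 5.51, and Tpm3 9.54 and 3.27. In the developmental list Myl4, the embryonic and atrial light chain, had 7.79 and 10.8, the adhesion gene Ncam1 4.55 and 2.56, and Cdh15, the cadherin of myoblasts, 5.63 and 1.69. The myosin heavy chain genes themselves, which define fibre types, had weak promoters or none. Myh1 (type IIx) had signals of 0.981 and 0.528, Myh8 (perinatal) 0.825 in replicate 1 only, and Myh2 (IIa), Myh4 (IIb), Myh7 (slow) and Myh3 (embryonic) had none. Neither Tnnt2 nor Myh7b had a promoter peak in either library. At the Myh4 promoter the permissive list held peaks of 1.01 and 0.863, with a lowest FDR of 0.011 and 0.00873. For fast fibre genes the share passed in 3 other settings: a window of 250 bases (q = 0.0417), a window of 2500 bases (q = 0.00876) and the permissive list (q = 0.0490).

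Regulators of the muscle lineage were open at 18 of 22 promoters (q = 0.131). The MEF2 genes Mef2a (percentile 88.5 ± 2.47) and Mef2d (12.5 and 5.71), the serum response factor gene Srf (12.3 and 4.22) and Tead1 (8.90 and 5.91) had strong promoters, and Myod1, a master regulator of myogenesis, had signals of 6.94 and 1.76. Nfix had signals of 5.88 and 2.35, Tbx15 5.72 and 2.25, Six4 5.64 and 1.80, Maf 5.41 and 3.09, Tead4 5.23 and 2.04, Mef2c 4.12 and 1.47, Eya1 3.82 and 1.83, Sox6 3.16 and 1.48, Prox1 2.66 and 1.39, Vgll2 2.37 and 0.867, Myog 2.10 and 0.982, and Eya4 1.74 and 1.07. Pax7, the marker of satellite cells, Myf5 and Myf6 had promoter peaks in replicate 1 alone (1.47, 0.858 and 0.831), and Pax3 had none. In replicate 2 the permissive list held promoter peaks for Pax7 (0.729, lowest FDR 0.0112) and Myf5 (0.578, lowest FDR 0.00117). Satellite cell genes were open at 13 of 18 promoters (q = 0.593), among them the integrin gene Itgb1 (12.6 and 5.12), the Notch target Hey1 (10.7 and 5.50) and Spry1 (5.92 and 9.59), while Calcr, a gene of quiescent satellite cells, had no peak. Genes of the neuromuscular junction were open at 12 of 15 promoters (q = 0.278), among them the transcription factor gene Etv5 (18.7 and 8.32), Ufsp1 (11.2 and 5.39) and Chrnb1, an acetylcholine receptor subunit (12.9 and 4.39). Without replicate 2, the share passed for myogenic regulators (95.5%, q = 0.00416), satellite cells (88.9%, q = 0.0451) and the junction (93.3%, q = 0.0292).

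Of the 5 lists for tissues outside skeletal muscle, 4 had closed promoters for most genes and the neuronal list did not. Only 1 of 18 hepatocyte genes and 1 of 16 germ cell genes had an open promoter, and the shares were lower than among other genes (q = 1.1e-05 and 3.5e-05, Fisher's exact test). The open ones were Apob (0.937 and 1.15) and Dazl (7.48 and 3.37). The liver genes Alb and Apoa1 and the germ cell genes Ddx4 and Sycp1 had no peak. Keratinocyte and epithelial genes (4 of 17, q = 0.0056) and heart-enriched genes (5 of 16, q = 0.0397) were also lower. In the first of these lists Krt10 (8.64 and 3.43), Sfn (1.47 and 0.716) and Dsp (0.987 and 0.514) were open, with Krt5 and Krt14 closed. Ryr2 (1.45 and 0.647) and Gata4 (1.12 and 0.427) were open in the second, with Nppa and Myh6 closed. Neuronal genes were open at 10 of 18 promoters (q = 0.722), for example Map2 (4.69 and 1.99), Snap25 (2.63 and 2.73) and Camk2a (4.64 and 1.40), with Stmn2 and Slc17a7 closed. With a window of 2500 bases the keratinocyte call ended (q = 0.134), and the heart call ended in that window (q = 0.0760), in the permissive list (q = 0.260) and without replicate 2 (q = 0.0614). No setting of this test matched genes on the CpG ratio of their promoters (observed over expected). Its median was 0.235 for hepatocyte, 0.384 for germ cell, 0.395 for keratinocyte and 0.288 for heart genes.

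Markers of the other cell types of the tissue varied. Macrophage and leukocyte genes were lower, with 1 of 18 promoters open (q = 1.1e-05), that of Cd68 (0.764 and 0.762), and Ptprc and Csf1r closed. Their median CpG ratio was 0.216, and this test was not matched on it. Fibroblast and fibro-adipogenic genes were open at 14 of 18 promoters (q = 0.300), endothelial genes at 11 of 18 (q = 1.0), tendon and connective tissue genes at 8 of 12 (q = 1.0), Schwann cell genes at 8 of 15 (q = 0.717), adipocyte genes at 5 of 13 (q = 0.151) and erythroid genes at 3 of 11 (q = 0.0543), none of which passed. Open examples were Col1a1, a collagen (7.14 and 4.46), Gsn (5.78 and 2.11) and the receptor gene Pdgfra (3.86 and 2.92) for fibroblasts. For endothelium they were Eng (2.79 and 1.90), the VEGF receptor gene Kdr (1.68 and 1.76) and Esam (2.49 and 1.17), and for tendon Egr1 (14.0 and 8.44), Mkx (3.80 and 3.41) and Col12a1 (4.06 and 2.32). Schwann cell examples were the myelin gene Prx (9.69 and 5.66) and the myelination regulator Egr2 (7.21 and 3.78). Adipocyte examples were the lipase gene Lipe (12.3 and 7.48), Plin4 (8.23 and 2.28) and Gpd1 (4.78 and 1.31), of which Gpd1 also stood in the glycolysis list. Erythroid examples were Epor (2.49 and 1.11) and Tal1 (0.914 and 0.642). Closed in both libraries were Tcf21, Emcn, Vwf, Tnmd, Comp, Sox10, Adipoq, Plin1, Gata1 and Klf1. The fibroblast share passed as higher without replicate 1 (88.9%, q = 0.0486). The erythroid share passed as lower in 5 other settings, for example without replicate 1 (q = 0.0461) and without replicate 2 (q = 0.0425).

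**Figure D1:**
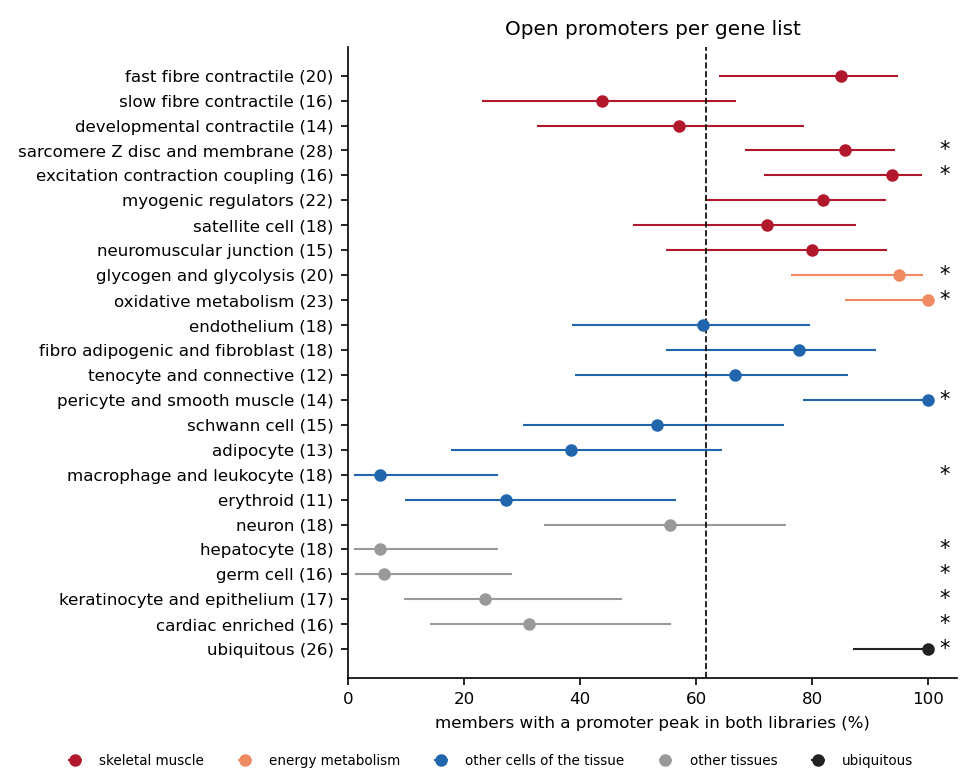
Percent of the members of each gene list with a promoter peak in both libraries (x axis), with Wilson 95% intervals and the number of members in brackets. The dashed line is the share of all protein-coding genes (61.7%), stars mark lists that passed the test, and the values run from 5.56% for macrophage and hepatocyte genes to the full list for oxidative (23), pericyte (14) and ubiquitous (26) genes.

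Ranking genes by promoter signal, with closed promoters tied at the bottom, set the ubiquitous genes apart. Their median percentile was 84.1, higher than the 50.2 of random lists of the same size (two-sided permutation test with 10000 lists, q = 0.0096). No other list passed, although the glycolysis genes had a median of 72.7 (q = 0.283), the oxidative genes 68.2 (q = 0.449), fast fibre genes 59.6 (q = 0.685) and slow fibre genes 33.6 (q = 0.675). A lower call was out of reach, because the lower bound of the random lists was itself the value of closed promoters (percentile 18.3). The adipocyte, macrophage, erythroid, hepatocyte, germ cell, keratinocyte and heart lists had their median at that value. Promoters rich in CpG sites were open in most genes (94.8% in the upper 3 deciles, 10.1% in the lower 3). The tests of open shares were not matched on CpG content. Median CpG ratios were 0.235 for hepatocyte, 0.216 for macrophage, 0.544 for oxidative and 0.664 for ubiquitous genes. CpG content was thus not separated from these calls. Coupling (0.264), sarcomere (0.305) and pericyte genes (0.301) had low ratios as well and were called higher. Against random lists with the same CpG content, fast fibre genes (q = 0.0048) and glycolysis genes (q = 0.0480) were higher and neuronal genes, with a median of 39.7, were lower (q = 0.0480). Ubiquitous genes kept their call there. No other list was called, oxidative, sarcomere, hepatocyte and macrophage genes among those. For lists whose median was the value of closed promoters this decides little, since no median can be lower.

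Around genes of the contractile apparatus and its regulators, open distal sites were more numerous than around other genes of the same length. Genes of excitation-contraction coupling had a mean of 6.0 shared distal regions within 50 kb, fast fibre genes 5.85, myogenic regulators 5.77, slow fibre genes 5.38, sarcomere and membrane genes 5.18, developmental contractile genes 4.93 and oxidative genes 4.43, where random lists had medians of 2.55 to 2.69. The size of the fast fibre excess depended on the library, with 12.2 regions against 3.45 in random lists without replicate 2 and 8.1 against 3.7 without replicate 1. Members with many such regions were Sgca, a sarcoglycan, with 18, in a window that overlaps that of the collagen gene Col1a1 of the fibroblast list (17 regions), Nfix with 15, and Bin1, the fast troponin gene Tnnt3 and Myog with 14 each. Tead1 had 13, and Mef2d, Tead4 and the stretch-responsive gene Ankrd2 had 12. Peak counts around several of these genes differed between the libraries: Tnnt3 had 56 and 17 distal peaks and Sgca 41 and 22. Among the myosin genes, Myh3 had 8 shared distal regions and Myh2 had 6, and Myh4, with 1 shared region, had 1 and 10 peaks per library. Over all genes the mean was 2.59, from 41807 shared distal regions.

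All 7 of these lists were higher (two-sided permutation test with 10000 length-matched lists, Benjamini-Hochberg over 24 lists): fast fibre genes and myogenic regulators with q = 0.0024, from the smallest p the lists could give (0.0002), coupling with q = 0.0032, slow fibre and sarcomere genes with q = 0.0038, oxidative genes with q = 0.0256 and developmental genes with q = 0.0336. No list was lower. Hepatocyte genes came nearest, with 1.5 regions (q = 0.107 in the permutation test). Just short of the threshold were pericyte and smooth muscle genes (4.64 regions, q = 0.0549), fibroblast genes (4.39, q = 0.0549), ubiquitous genes (3.88, q = 0.0648) and satellite cell genes (4.22, q = 0.0654). The remaining lists were junction genes (4.07), adipocyte (4.15), glycolysis (3.80), tendon (3.83), endothelium (3.50), macrophage (3.39), germ cell (3.19), Schwann (3.0), erythroid (3.0), heart (2.94), neuron (2.72) and keratinocyte genes (2.24), with q from 0.114 to 0.936. The call for oxidative genes ended without replicate 1 (q = 0.0898), without replicate 2 (q = 0.0736), in a window of 100 kb (q = 0.122) and for kilobases covered (q = 0.0684). That for developmental genes ended without replicate 2 (q = 0.0763), in windows of 20 kb (q = 0.0757) and 100 kb (q = 0.0624) and for kilobases covered (q = 0.0684), and that for slow fibre genes ended in the window of 100 kb (q = 0.0624). In other settings 6 further lists passed as higher. These were fibroblast genes (for example without replicate 2, q = 0.0233), pericyte genes (without replicate 1, q = 0.0228), ubiquitous genes (without replicate 1, q = 0.0144), junction genes (without replicate 2, q = 0.0233), and satellite cell (q = 0.0080) and glycolysis genes (q = 0.0181) within 20 kb, so the excess was not particular to contractile genes.

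**Figure D2:**
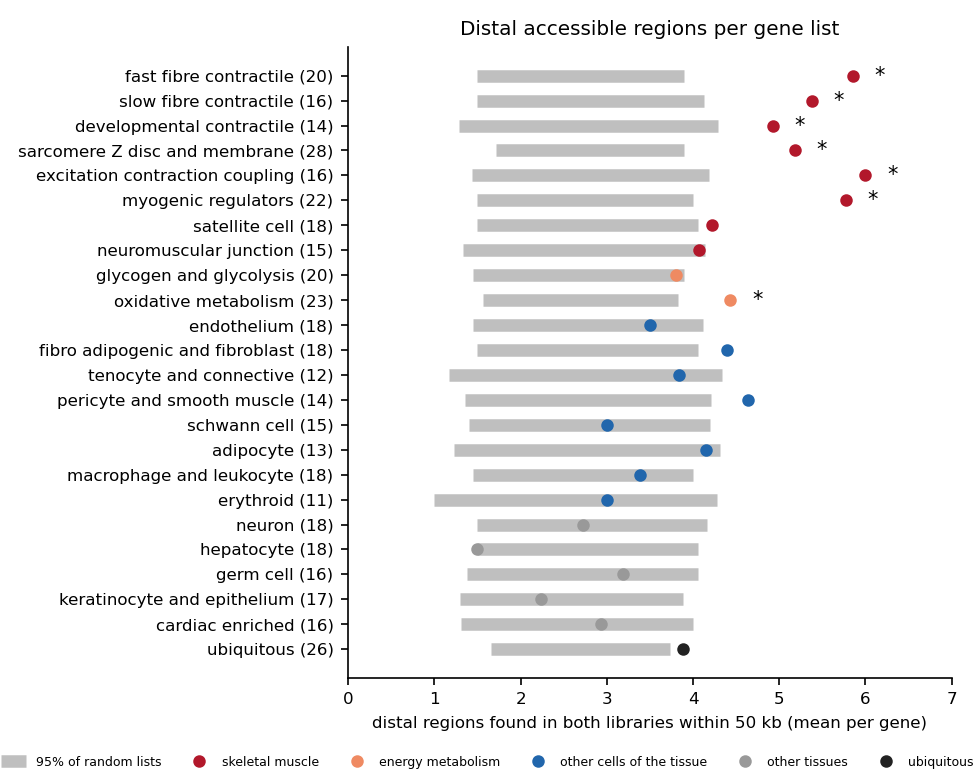
Mean number per gene of distal open regions found in both libraries within 50 kb of a start (x axis), for each gene list with its number of members in brackets. Grey bars span 95% of 10000 length-matched random lists, stars mark lists that passed the test, and the coupling list reached 6.0 and the hepatocyte list 1.5.

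Footprints carried the binding sequences of widely expressed factors. Matches to the site of NRF1, a regulator of mitochondrial and housekeeping promoters, were 53.1 and 58.6 times as dense in footprints as in the rest of the same peaks, and those of the insulator protein CTCF 34.4 and 69.7 times. Ratios were 65.5 and 21.3 for the nuclear factor I family (NFI), from 55 and 113 matches in footprints and only 3 and 17 outside. For the neuronal repressor REST they were 20.8 and 44.2. The RFX site had ratios of 23.2 and 20.8 on 13 matches in footprints of each library and 2 outside. The cyclic AMP response element (CRE) had 16.9 and 10.6. SP and KLF factors had 7.49 and 8.11, ETS factors 4.63 and 2.68, YY1 2.11 and 1.87, NFY 1.97 and 1.54, and the CACGTG E-box of USF and MYC 2.00 and 1.42. The myogenic E-box CAGCTG, bound by MYOD1 and myogenin, was only slightly denser in footprints (1.22 and 1.16). Matches for GATA factors (0.292 and 0.363), the steroid receptors (0.482 and 0.470), POU factors (0.695 and 0.633) and RUNX (0.728 and 0.824) were less dense in footprints than in the rest of the peaks. The muscle motifs of MEF2 (0.874 and 0.579), TEAD (0.935 and 0.875), serum response factor (0.829 and 0.952) and the estrogen-related receptors (0.647 and 0.649) were not called. Nor were AP-1 (0.931 and 0.811), the TATA box (0.976 and 0.944) and HNF4 (1.05 and 0.815), and HNF1 had too few matches for a ratio.

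Of the 25 motifs, 12 were higher, 4 were lower and 9 were not called, a call requiring the same direction in both libraries (Fisher's exact test on bases, Benjamini-Hochberg over motifs; bases are not independent). In both libraries, 8 of the 12 also exceeded every column-shuffled version of their consensus, while REST and RFX had no shuffled matches to compare and YY1 and CAGCTG did not exceed all of theirs. For YY1 the log2 was 1.08 and 0.90, and the largest shuffled value 1.25 and 1.68. Shuffled versions of POU (mean log2 of -0.91 against -0.59) and RUNX (-0.66 against -0.37) were even less dense in footprints, so these sites were not depleted beyond base composition. For MEF2 this held in replicate 1 (shuffled -1.35 against -0.19) but not in replicate 2 (-0.74 against -0.79). Shuffled means were also lower for the TATA box (-1.04 against -0.06) and HNF4 (-0.77 against -0.12). The same held for serum response factor (-0.74 against -0.17), TEAD (-0.39 against -0.14) and AP-1 (-0.43 against -0.20). It was reversed for the estrogen-related receptors (-0.47 against -0.63). Of the motifs not called, only the TATA box exceeded every shuffled version in both libraries. The CAGCTG ratio (mean log2 of 0.25 ± 0.05) did not exceed the mean of its shuffled versions (log2 of 0.32), and the SP and KLF consensus had a shuffled mean log2 of 2.07 against 2.96 ± 0.08. The shuffled CAGCTG values varied widely (SD 0.69 and 0.56). Shuffling kept base composition but not pairs of neighbouring bases such as CpG. For CAGCTG and for motifs with CpG it therefore cannot separate the site from CpG content. Footprints had a GC content of 64.5% and 62.4%, against 56.6% and 54.3% in the rest of the peaks. MEF2 and AP-1 sites were among those called lower when only bases within 50 of a footprint served as background (mean ratios 0.699 and 0.834), when a match was assigned to its central base, and without replicate 1. Assignment to the central base moved ratios by more than 1.5-fold in at least 1 library for NRF1 (137 and 83.5), CTCF (56.3 and 106), NFI (66.7 and 205), YY1 (2.75 and 3.07), MEF2 (0.545 and 0.349), AP-1 (0.602 and 0.521) and the steroid receptors (0.288 and 0.347), and the nearby background moved RFX (19.7 and 35.1).

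**Figure D3:**
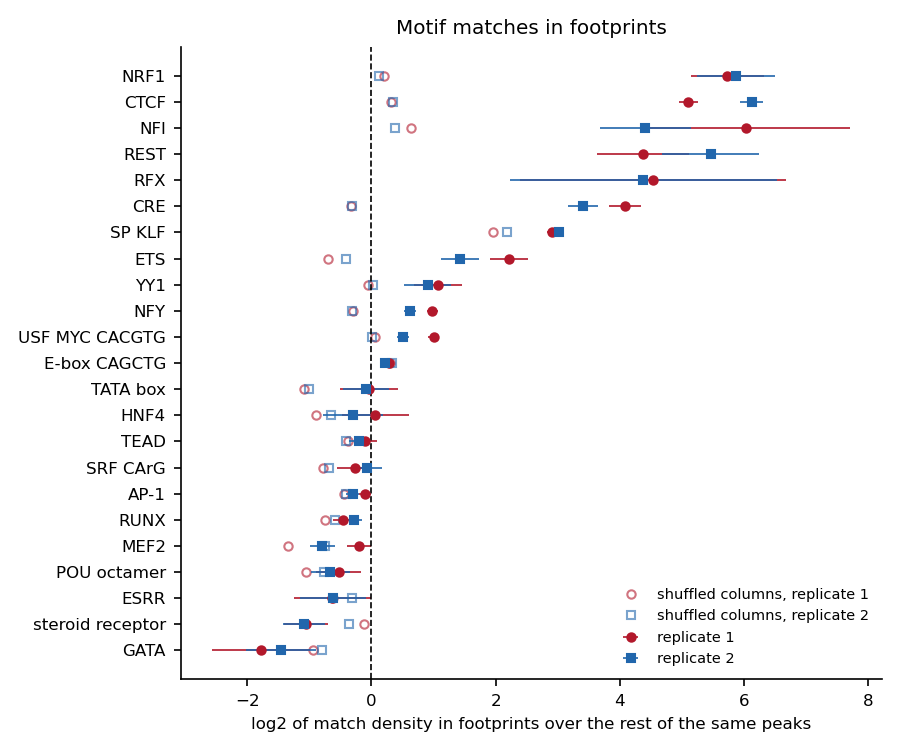
Density of motif matches in footprints over that in the rest of the same peaks (x axis, log2), with 95% intervals from counting error for replicate 1 (circles) and replicate 2 (squares), and the mean of column-shuffled consensus sequences as open symbols. NRF1 stood at 5.73 and 5.87 and GATA at -1.77 and -1.46, and HNF1 is left out for lack of matches.

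Footprints lay mostly in peaks, and strong peaks almost always held footprints. Of all footprints, 68.2% and 69.5% overlapped a peak (mean 68.8%), and 90.7% and 91.5% of peaks held at least 1 footprint (mean 91.1 ± 0.578%). From the weakest to the strongest of 4 signal bins the share of peaks with a footprint went from 79.5% to 99.6% in replicate 1 and from 79.4% to 99.9% in replicate 2. Of the footprints of each library, 55.9% and 46.0% overlapped one of the other library. In regions open in both libraries 70.3% and 61.5% did, against 23.8% and 20.8% after moving those of the other library by 100 bases. These regions had a median width of 200 bases, and moved footprints were not kept inside them. That may lower the values after moving, so the gap can overstate agreement in position.

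Distal regions near muscle genes were compared with other distal regions for the same motifs, to ask which binding sites were more frequent there. MEF2 sites occurred in 3.98% of the 728 regions within 50 kb of the 142 muscle genes and in 2.38% of the 41079 others (odds ratio 1.70, exact p = 0.00974, q = 0.243). TEAD sites occurred in 3.98% and 2.55% (odds ratio 1.58, exact p = 0.0238, q = 0.298). The CAGCTG E-box occurred in 31.3% and 29.7%, CTCF sites in 9.07% and 9.27%, and AP-1 sites in 8.38% and 8.41%. None of the 25 motifs passed Fisher's exact test after adjustment, and 2 had an unadjusted p under 0.05. Without replicate 2, MEF2 passed (odds ratio 1.81, q = 0.0361), and without replicate 1 it did not (odds ratio 1.23, q = 0.983).

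Males carry a single X chromosome, and open sites on X were compared with those on autosomes. X had 12.5 and 14.5 peaks per Mb, below every autosome (24.6 to 53.5 in replicate 1 and 27.3 to 55.0 in replicate 2, lowest on chromosome 14 and highest on chromosome 11), and 0.372 and 0.406 times the density of all autosomes together (mean 0.389 ± 0.0238). The median signal of X peaks was 0.599 and 0.581 times the median of the autosomes (mean 0.590 ± 0.0131). Promoters of 46.0% of the 948 X-linked genes were open in both libraries, against 62.9% of autosomal genes, and the median signal of open CpG-rich promoters was 3.95 and 2.10 on X against 8.21 and 4.50 on autosomes. Chromosome Y held 42 and 44 peaks (0.477 and 0.499 per Mb). No p-value was computed for these values, and explanations for them are examined under the other observations. Among peaks at or above the median signal the X density was 0.234 and 0.242 of the autosomes (mean 0.238). The median signal ratio was 1.06 and 0.876 (mean 0.966). Peaks of X and of autosomes were cut at the same signal there, which draws their medians together. This ratio therefore cannot show whether X peaks were weaker.

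**Figure D4:**
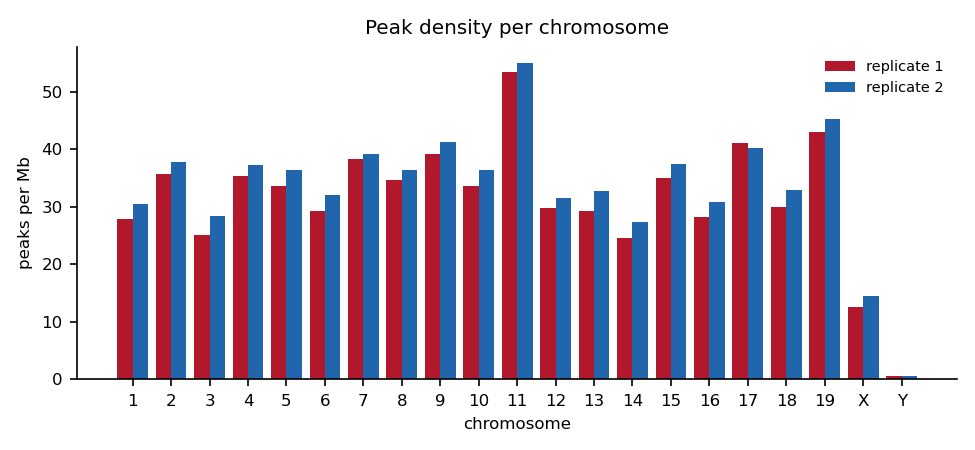
Peaks per Mb of sequence without gaps (y axis) for each chromosome (x axis) in replicate 1 (red) and replicate 2 (blue). X stood at 12.5 and 14.5 peaks per Mb and chromosome 11 at 53.5 and 55.0.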

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

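Alternatives marked below as added were chosen after the data were seen, and their tests with them. No paired analysis was possible because there is 1 group.

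Of the 11 lists called for open promoters, 5 kept their call in every setting (germ cell, hepatocyte, macrophage, glycolysis and ubiquitous genes), none of which matched genes on CpG content. Of the 7 called for distal regions 4 did (coupling, fast fibre, myogenic regulators and sarcomere), and the 1 call for promoter signal held throughout. No called list turned direction, while lists without a call did so in 14 cases for open promoters, 13 for promoter signal and 7 for distal regions. With peaks at or above the median signal there were 42778 peaks per library by construction, 42.1% of them at promoters. In that setting 3 lists had a higher open share instead of 6. Mean X over autosome ratios were 0.238 for density and 0.966 for signal (1.06 and 0.876 per library). The permissive list gave 138831 peaks, 72.1% of them shared, 10 lists with a higher open share, 88.8% of footprints in peaks and 83.2% of peaks with a footprint. Reciprocal overlap gave 66.6% shared peaks and a Spearman correlation of 0.820. With a window of 250 bases 18.8% of peaks were at promoters, and with 2500 bases 3 lists had a lower open share instead of 5. Matching on CpG ratio gave 3 lists higher and 1 lower for promoter signal. Footprints wholly inside a peak made up 64.9%, with 89.96% of peaks holding one. Motifs called lower in footprints, 4 in the chosen setting, were 7 with the background near footprints and 7 with matches at their central base (added). Over the 2 libraries taken alone they ranged from 4 to 9, and motifs called near muscle genes from 0 to 1. Apart from the number of peaks at or above the median, the cause was not tested.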

Other observations

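The gene families, the single genes, and the library ratio, X and strict-list patterns below, with their tests, were chosen after the results were seen.

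Large gene families were mostly open or mostly closed. Promoters were open in both libraries for 7 of 1134 olfactory receptor genes, 1 of 328 vomeronasal receptor genes, 3 of 57 keratin-associated genes and 1 of 64 defensin genes. They were open for all 78 mitochondrial ribosomal genes, all 46 subunits of respiratory complex I, 80 of 82 cytosolic ribosomal genes, 37 of 40 proteasome genes, 340 of 394 zinc finger genes and 53 of 67 clustered histone genes. Among the exceptions were the ribosomal genes Rpl10l and Rpl39l, known from testis, Psma8, from the proteasome of spermatocytes, and Psmb11, from that of the thymus. In the protocadherin clusters 3 of 56 promoters were open, namely those of Pcdhgc3, Pcdhac1 (0.697 and 0.509) and Pcdhac2 (0.596 and 0.413). All 12 families passed Fisher's exact test, 6 as higher and 6 as lower, the Hox genes among the lower ones with 15 of 39 (q = 0.00443).

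A few single genes were looked up by hand, and no list or test stands behind them. Tbx4, known from the hind limb, had promoter signals of 1.28 and 0.656 with 8 shared distal regions, and Tbx5, known from the forelimb, had no promoter peak and no distal region. Mymk, the gene for the fusogen that joins myoblasts, had a promoter peak (2.47 and 1.80) and 10 shared distal regions. Hox genes were open at 6 of 11 promoters in cluster A, 1 of 10 in B, 3 of 9 in C and 5 of 9 in D.

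Regions near genes of the muscle lists had a higher ratio of replicate 1 to replicate 2 than regions near genes of other cell types, by a median log2 of 0.19 where random gene sets reached 0.09 (1200 and 754 regions). The difference was 0.21 after correction for signal level and 0.22 after correction for GC content, so the tables argue against both as the cause. Fast fibre (1.31-fold), coupling (1.32-fold), sarcomere (1.23-fold) and glycolysis genes (1.30-fold) passed a permutation test (q = 0.0120 for each, from the smallest p that 1000 draws could give), as did oxidative genes (1.20-fold, q = 0.0384). Slow fibre (1.03-fold, q = 0.896), developmental (1.13-fold, q = 0.562), junction (1.10-fold, q = 0.706), satellite cell (1.07-fold, q = 0.896) and regulator genes (1.17-fold, q = 0.123) did not. A larger share of muscle fibre nuclei in replicate 1 would give such a difference. Its test rested mainly on the difference itself and so cannot decide the question. Of the 8 lists of other cell types, 0 lay above and 0 below the random range, and slow fibre genes did not follow the difference. The cause stays open.

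Chromosome X had fewer peaks, and weaker ones over the whole strict list. Its open CpG-rich promoters had 0.473 times the autosomal signal, which fits a single copy in males, although unequal mapping of B6 and CAST alleles, which would also change this ratio, was not tested. The single copy did not account for the peak density (0.733 of the lowest autosome after doubling the signal threshold for autosomes), nor did gene density (0.910 of the lowest autosome in peaks per gene) or repeat sequence (0.651 of the lowest autosome per Mb without repeats), each value being the higher of the 2 libraries. In peaks per gene X had 2.15 and 2.51, and the lowest autosome was chromosome 7 with 2.68 and 2.75. The next lowest had 3.32 (chromosome 14, replicate 1) and 3.50 (chromosome 17, replicate 2). Copy number and gene density together brought X to 0.938 of the lowest autosome in the higher library, which is undecided. What else lowers the number of X peaks stays open.

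In each library some peaks of the permissive list had at least the median signal of strict peaks but overlapped no strict peak (243 and 289 peaks). Their own FDR was not looked up, so whether each missed the strict threshold is not known. Of them, 8.64% and 7.96% lay near genes of the muscle lists, against 2.61% and 2.18% of strict peaks with such signal (Fisher's exact p = 2.4e-06 and 1.6e-07). Nfix had 3 and 8 of these permissive peaks, Bin1 1 and 3, Tnnt3 1 and 3, and Myh1, Myh4 and Myh8 1 and 1 each. Other genes had them in 1 library only, such as Ldb3 and Mylk2 (3 and 0 each). Each peak was counted for every muscle gene within 50 kb, so neighbouring genes can share the same peak. Peaks of 1 locus, such as those near Nfix, entered Fisher's test separately, so its p-values treat them as independent. These permissive peaks had at least 1.61 times as many other peaks within 5 kb as strict peaks of equal signal (3.77 against 2.15 in replicate 1, 3.41 against 2.12 in replicate 2). A raised level of cleavage around them would fit this, but only if their FDR kept them off the strict list. Their share of repeat bases was 8.84% against 6.87% in matched peaks in replicate 1, beyond the range of matched draws, and 9.52% against 8.52% in replicate 2, within it (1.12 times, the lower ratio), which is undecided. Near genes of the muscle lists these permissive peaks numbered 21 and 23, against 1078 and 963 strict peaks with such signal. Counts of strict peaks at the most open muscle loci may therefore be too low, only slightly so over the muscle lists at this signal level. For weaker peaks the size stays open.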
